A study of Mus musculus with 8 samples.

How the data were processed

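RNA was sequenced from total RNA with an Illumina TruSeq RNA kit as paired reads of 100 bases on an Illumina HiSeq instrument, per the labels' protocols. The samples were 8 libraries of mouse embryonic stem cells, C57BL/6 and male, derived from blastocysts of embryonic day 3.5 and kept in 2i ground state medium, which blocks differentiation signals. Of these, 4 libraries were iPHet, the control genotype, and 4 were iPKO, the Prmt5 knockout. The name iPHet reads as heterozygous, so the control need not have both copies of Prmt5 intact. All cells received 2 µM 4-hydroxytamoxifen for 48 hours, the treatment used to bring about the deletion at Prmt5, and then fresh medium. The labels name a single line per genotype for most experiments, so genotype and line were not separable. The labels do not say whether libraries of a genotype came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

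The authors deposited FPKM values (fragments scaled to transcript length and to the library's fragments) per gene and library, with lower and upper confidence bounds and a status, per the file headers. Reads were trimmed with Trimmomatic and the genome build was mm10, per the submitters' processing notes. The aligner, the program that made the FPKM values and all versions are not given in the sources used here, and neither is strand. FPKM values were computed per library, not pooled, per the file headers. Any scaling of FPKM between libraries by the authors is not stated. Genes that share sequence with copies elsewhere, and genes that overlap on the genome, can exchange reads in such values.

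Each file held 39013 rows for 38991 gene identifiers. The rows of 19 identifiers found at more than 1 locus were summed. Symbols and coordinates were taken from the files, and 96% of identifiers were in GENCODE release vM21, used for gene types. Of the matched identifiers, 99.8% overlapped the annotated locus. The absolute depth is unknown because the files hold no counts. Relative depth, read from the mode of the ratios of very low values to iPHet 1, ran from 0.766 in iPHet 3 to 1.24 in iPKO 1. Between 2 and 5 rows per library had a failed estimate, and 11 tested genes had one in some library. An exact 0 can be such a failure, since 13 of 8139 protein-coding genes with a mean of at least 5 FPKM were listed at 0 in some library.

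The design written before the data were examined foresaw a count test for count files and limma for FPKM alone. Because the files held FPKM, the test was limma 3.58.1 with an intensity trend in R 4.3.3. Files were read with the R package data.table, version 1.17.8. Values were log2(FPKM + 1), so fold changes of low genes are understated. Genes with a mean of at least 1 FPKM in either genotype were kept, which left 12462 genes, 11171 of them protein-coding. All 8 libraries entered, with no covariate, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. A 2-fold change was an absolute log2 change of at least 1. The words rose and fell are used of called genes. Ratios quoted as fold are of mean FPKM.

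Gene lists, 27 in number with 545 entries, were fixed before the data were examined and tested with camera at a preset correlation of 0.01. A list needed at least 3 tested members, which 26 lists had. Chromosomes were tested the same way. The 9 list entries without a match (Tubb3, Zscan4a, Dux, Eif1a-ps2, Cdt1, Gins2, Slc7a5, Kcnq1ot1 and Rpl13) were not analysed here. Pidd1, Tigar, Tex13b and Prmt9 carry the symbols Lrdd, 9630033F20Rik, Tex13 and Prmt10 in the files. Named genes were chosen by a fixed rule. It took the 12 largest rises and the 12 largest falls among called genes with separate groups and a mean of at least 5 FPKM, leaving out unnamed genes and small RNAs. It added up to 4 members of each list with the smallest p, and Prmt5, Trp53, Mdm4, Pou5f1, Nanog, Dazl and Xist. Isoform usage was not tested because values per transcript were not analysed here.

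Libraries were compared over 8123 protein-coding genes. Between libraries 1 and 3, or 2 and 4, of a genotype the variance was 1.56 to 2.12 times that of the authors' bounds. Between the other libraries of a genotype it was 14 to 20.8 times. The calibration of the bounds is unknown, so this does not show whether paired libraries are separate cultures. They entered the main test as separate libraries because the design written before the data were examined has all 8, with pair averages as alternatives chosen after this was seen. Between the genotypes, deviations from the group means over all tested genes correlated at 0.104, 0.162, 0.204 and 0.107 for the numbers 1 to 4. All exceed the 0.1 taken as the limit for paired numbers, a pairing that comes from the data and not from the labels. Over all tested genes it is not clearly specific to the number. Libraries with different numbers that were both odd or both even correlated at 0.077 to 0.124, the highest being iPHet 2 with iPKO 4. Over protein-coding genes the values were 0.421 to 0.455 for the same number and 0.329 to 0.366 for those others. These ranges do not overlap. Between genotypes over the same genes, 1 with 2 and 3 with 4 correlated at -0.378 to -0.331. For 1 with 4 and 2 with 3 the values were -0.443 to -0.417. Part of the resemblance therefore went with libraries 1 and 2 against 3 and 4, and was not shown to be specific to the number.

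The scripts were tested on simulated data with known answers. With 8 independent libraries and 200 changed genes among 12462, the test called 52%, 90% and 98% of genes changed by 0.5, 1 and 2 on the log2 scale, and 3.5% of its calls were false. Paired libraries were then simulated without a genotype change under 2 models, in 20 draws each. With the cultures of each pair drawn independently, the 8-library test made 634 false calls at the median (519 to 706), and the test of pair averages made 0 (0 to 1). The other model, added after those results were seen, keeps each gene's odd minus even difference in both genotypes. The 8-library test then made 1 false call at the median (0 to 8). The pair-averaged fit of protein-coding genes with an odd/even term made 9.5 (1 to 70). Under the first model that fit called 0% of the genes changed by 2, and under the other 100%.

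Alternatives planned beforehand were quantile normalization, no filter on low values, a mean of at least 5 FPKM, limma without the trend, a pseudocount of 0.1, the replicate number as a block, an estimated correlation between list genes and leaving out each library in turn. Those added after seeing the data were averages of the paired libraries, a term for odd against even numbers, an estimated correlation within pairs, protein-coding genes only, and the odd-numbered or even-numbered libraries alone. Prmt5 was also compared with an exact two-sided permutation test.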

Results

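The series compared gene expression in mouse embryonic stem cells of a control genotype and of a Prmt5 knockout. Prmt5 encodes the arginine methyltransferase of the Sm proteins, core proteins of the spliceosome. The title of the series concerns whether PRMT5 is needed for the specification of primordial germ cells, the precursors of sperm and eggs. RNA was sequenced from 4 iPHet control libraries and 4 iPKO knockout libraries. The summed FPKM per library ran from 411827 to 458856, and 11640 to 12099 genes reached 1 FPKM. The absolute depth of the libraries is unknown, and their number limits the precision.

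Prmt5 was lower in every iPKO library than in every iPHet library. Its mean was 62.5 ± 10.4 FPKM (SD, n = 4) in iPHet and 13.4 ± 1.56 FPKM (SD, n = 4) in iPKO, which was 4.66-fold lower and left 21.5% of the control level. The gene (ENSMUSG00000023110) lies on chromosome 14 from 54507187 to 54517525 of mm10. On the log2 scale it fell by 2.13 (SE 0.13, limma adjusted p = 0.000171), by 2.06 in the odd-numbered and by 2.21 in the even-numbered libraries. An exact two-sided permutation test gave p = 0.0286, the smallest that 4 against 4 libraries allow. The gene-level value includes reads from exons outside any deleted part. With paired libraries averaged the limma adjusted p was 0.191, and with an odd/even term as well 0.0809. Of the pair-averaged fits, only that of protein-coding genes with the term called Prmt5 (0.00703). The fit with an estimated correlation within pairs, which does not average them, also called it. Protein-coding pair averages without the term called 0 genes.

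**Figure D1:**
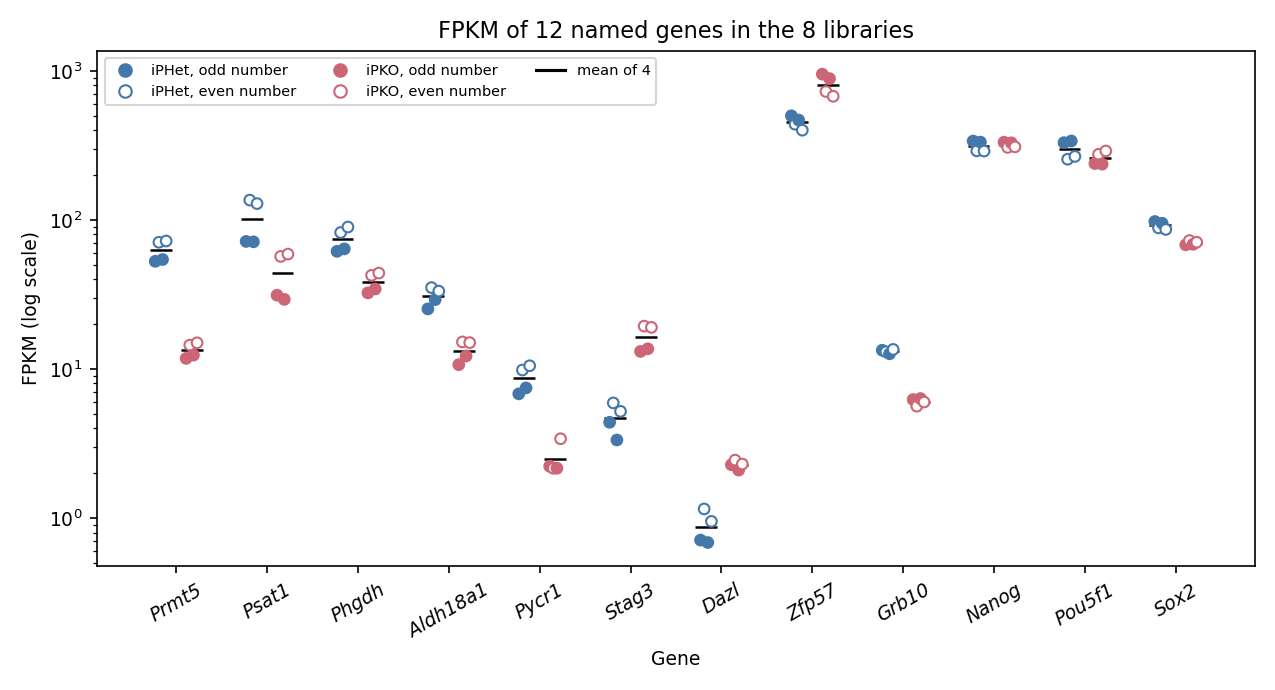
FPKM on a log axis of 12 genes in the 4 iPHet (blue) and 4 iPKO (red) libraries, with filled points for libraries 1 and 3, open points for libraries 2 and 4, and bars for the mean of 4. Prmt5 averages 62.5 FPKM in iPHet and 13.4 FPKM in iPKO, and Nanog averages 313 and 319 FPKM.

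The largest rises among well expressed genes included Stag3, a cohesin subunit of meiotic chromosomes, which went from 4.72 ± 1.11 to 16.3 ± 3.37 FPKM (SD, n = 4 each, 3.46-fold higher). Orc4, a subunit of the origin recognition complex, rose from 27.7 ± 2.12 to 63.3 ± 2.87 FPKM (SD, n = 4 each). Prpf39, a factor of U1 small nuclear ribonucleoprotein, rose from 12.1 ± 0.665 to 28.0 ± 1.35 FPKM (SD, n = 4 each). Snapc4, a subunit of the complex that starts transcription of small nuclear RNA genes, rose from 26.1 ± 1.81 to 56.4 ± 1.54 FPKM (SD, n = 4 each). Med17, a Mediator subunit, rose 2.41-fold, Tyw5 2.33-fold and Ptprv 3.29-fold. On the log2(FPKM + 1) scale, the largest falls after Prmt5 were those of Susd2 (2.86-fold lower) and Cox6b2 (2.97-fold lower), a subunit of cytochrome c oxidase. Pycr1, the last enzyme of mitochondrial proline synthesis, fell from 8.67 ± 1.80 to 2.49 ± 0.613 FPKM (SD, n = 4 each, 3.48-fold lower).

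Further falls were those of Tm7sf2, a sterol reductase, at 2.86-fold, Trh, the thyrotropin-releasing hormone precursor, at 2.62-fold, Fkbp11 at 2.71-fold, Ifrd2 at 2.49-fold, Dhrs4 at 2.51-fold and Pcolce2 at 2.49-fold. The tubulin gene Tuba1a fell from 167 ± 17.8 to 72.5 ± 21.5 FPKM (SD, n = 4 each). As3mt and Hpn closed the list of rises at log2 changes of 1.06 and 1.04. Erdr1 and H2-Q5 rose 3.45-fold and 3.08-fold, but both have near-identical copies and their values are uncertain. Cpne1, which rose 2.64-fold, overlaps Rbm12, Tm7sf2 overlaps Vps51, Orc4 overlaps Mbd5 and Acvr2a, and Prpf39 overlaps Fkbp3. Ptprv overlaps Gm10535, Tyw5 overlaps 9430016H08Rik and Snapc4 overlaps Gm13562. Reads of all such pairs can be exchanged. Hpn was not called without any single library except iPKO 2 (limma adjusted p of 0.0565 to 0.0905), Susd2 without any except iPKO 1 or 3 (0.0531 to 0.0846), and Pcolce2 without iPHet 2 or 4 or iPKO 1 (0.0524 to 0.0542).

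Across the transcriptome 1973 of 12462 genes were called, 785 higher and 1188 lower in iPKO, with a median absolute log2 change of 0.47. Of these, 1957 had no overlap between the genotypes. Among all tested genes 25.1% had none, against a share by chance of 2.9% for 8 exchangeable libraries and of 33.3% with each pair of libraries (1 and 3, or 2 and 4) as 1 unit. At least 2-fold were 116 genes, 66 higher and 50 lower, of which 71 were protein-coding, and with a pseudocount of 0.1 the number was 278 (151 higher and 127 lower). The replicate number as a block gave 3427 genes (1355 higher and 2072 lower), and quantile normalization gave 936 higher and 946 lower. Averages of the paired libraries, 2 against 2, gave 7 genes, and the fit of protein-coding genes with these averages and an odd/even term gave 198 (81 higher and 117 lower), 180 of them among the 1973. Of the 79 called named genes, 31 were also called in that fit, among them Stag3, Orc4, Prpf39, Snapc4, Pycr1, Cox6b2 and Tuba1a. Over all tested genes the same fit called 6 genes and ended the calls of 78 named genes. Prmt5 was not called there either (limma adjusted p = 0.0809), and protein-coding pair averages without the term called 0 genes. In simulated data with a shared odd/even difference and no genotype change, the protein-coding fit with the term made up to 70 false calls. Without iPHet 4 the count over all genes was 1270. In simulated data with no genotype change the 8-library test called 634 genes at the median where the pairs were drawn as independent cultures, and 1 where the odd/even difference was shared. Of the gene lists 4 were called, a number that 20 of the 35 possible groupings of the libraries reached. With an estimated correlation between list genes 0 lists were called.

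**Figure D2:**
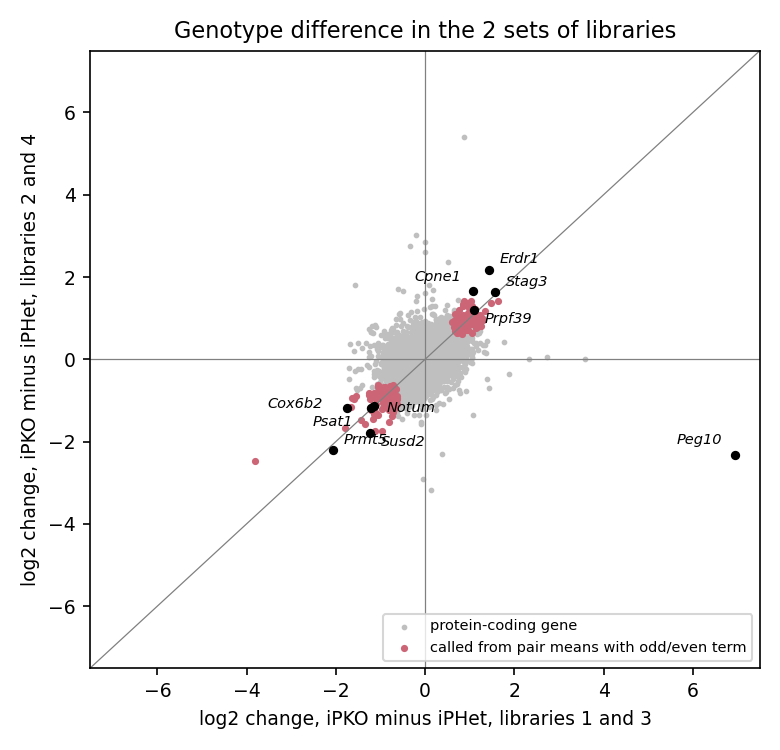
Each point is a protein-coding gene, with the log2 change from iPHet to iPKO in libraries 1 and 3 on the x axis and in libraries 2 and 4 on the y axis. Red points are the 198 genes called from pair averages with an odd/even term, and black points are labelled genes. Across 11171 genes, which are not independent replicates, the Pearson correlation is 0.422 (0.185 across all 12462 tested genes, with a Spearman correlation of 0.395), and Peg10 lies far to the right because several of its libraries are listed at 0.

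The transcription factor ATF4 acts in the integrated stress response. Of 18 tested members of the integrated stress and ATF4 list, 11 fell, 0 rose and 7 were not called, and 12 fell when adjusted over the list alone. Psat1 and Phgdh, enzymes of serine synthesis, fell from 102 ± 35.2 to 44.1 ± 16.0 FPKM and from 74.4 ± 13.8 to 38.4 ± 5.78 FPKM (SD, n = 4 each). Shmt2 and Aldh18a1, enzymes of mitochondrial folate and of proline metabolism, fell from 72.9 ± 7.13 to 36.6 ± 7.52 FPKM and from 30.8 ± 4.40 to 13.3 ± 2.20 FPKM (SD, n = 4 each). Mthfd2, Vldlr, Chac1, Nupr1, Trib3, Slc3a2 and Atf4 itself also fell, while Asns (403 and 357 FPKM) and Ddit3 (5.33 and 5.39 FPKM) were not called. The list's median log2 change was -0.63, with a camera adjusted p = 0.00035 and an adjusted p = 0.5 with an estimated correlation. In the pair-averaged fit of protein-coding genes with an odd/even term 6 members were called, all lower. Over all tested genes that fit called 6 genes in total, and Psat1 was not among them (limma adjusted p = 0.203). Psat1 was not called without iPHet 2 or 4 or iPKO 1 or 3 (limma adjusted p of 0.0911 to 0.0979).

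Of 16 tested members of the later germ cell list 6 rose, 1 fell and 9 were not called, or 8 rose and 1 fell adjusted over the list alone, at a median log2 change of 0.44. Besides Stag3, Dazl, an RNA-binding protein of germ cells, rose from 0.876 ± 0.220 to 2.28 ± 0.144 FPKM (SD, n = 4 each, limma adjusted p = 0.0035). Ddx4, Piwil2, Tex13 and Rpl10l also rose. Tdrd12, a factor of the piRNA pathway, fell from 17.7 ± 1.74 to 10.3 ± 2.11 FPKM (SD, n = 4 each). Rpl10l resembles a housekeeping ribosomal gene, so its value is uncertain. The camera adjusted p was 0.00035, with adjusted p = 0.22 with an estimated correlation and 0.057 with a minimum of 5 FPKM. In the pair-averaged fit of protein-coding genes with an odd/even term 2 members were called, Stag3 and Rpl10l, both higher. Dazl and Tdrd12 were not (limma adjusted p of 0.0633 and 0.0943). Over all tested genes that fit called neither Stag3 nor Rpl10l (limma adjusted p of 0.157 and 0.203).

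Several p53 target genes rose while p53 itself was not called. Trp53 was 138 ± 13.1 FPKM in iPHet and 153 ± 22.5 FPKM in iPKO (SD, n = 4 each, limma adjusted p = 0.471). Of 33 tested targets 8 rose and 1 fell, or 9 and 2 adjusted over the list alone. Aen, a nuclease, rose from 16.1 ± 1.64 to 30.04 ± 2.01 FPKM and Mdm2, the ubiquitin ligase of p53, from 66.4 ± 10.2 to 100.0 ± 3.91 FPKM (SD, n = 4 each). Pmaip1, Lrdd, Ercc5, Polk, Ei24 and Ccng1 rose, and Plk3 fell. Cdkn1a, the cell cycle inhibitor, was not called at 119 ± 44.1 and 126 ± 41.4 FPKM, nor was Mdm4 at 49.3 ± 3.89 and 52.1 ± 5.90 FPKM (SD, n = 4 each). The list's median log2 change was 0.19 over all libraries, 0.01 in the odd-numbered and 0.29 in the even-numbered ones. The camera adjusted p was 0.0015, with adjusted p = 0.68 with an estimated correlation. In the pair-averaged fit of protein-coding genes with an odd/even term Aen was the 1 member called. Over all tested genes that fit did not call Aen (limma adjusted p = 0.203). In the odd-numbered libraries alone the list's adjusted p was 0.51, and in the even-numbered ones 2.1e-06. Among 20 genes of the apoptosis machinery Pmaip1 rose, and Bad and Cycs fell. Adjusted over the list alone 1 rose and 7 fell, and the list was not called (camera adjusted p = 0.48). Bad overlaps Gpr137. Cycs was not called with the replicate block (limma adjusted p = 0.0774) or without any single library except iPKO 4 (0.0569 to 0.113).

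**Figure D3:**
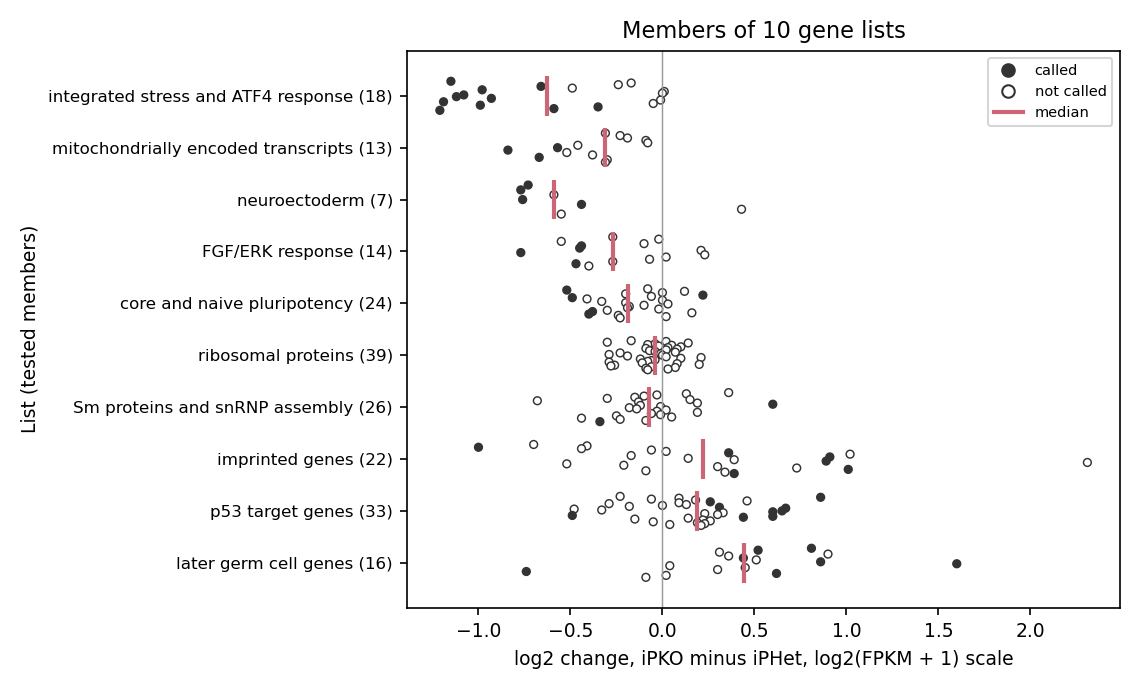
Log2 change from iPHet to iPKO, on the log2(FPKM + 1) scale, of every tested member of 10 gene lists, with filled points for called genes, open points for others and a red bar at the median. The ATF4 list has a median of -0.63 and the later germ cell list a median of 0.44.

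The core pluripotency genes stayed strongly expressed. Nanog was 313 ± 26.2 FPKM in iPHet and 319 ± 13.4 FPKM in iPKO, and Pou5f1 298 ± 42.7 and 260 ± 26.7 FPKM (SD, n = 4 each), with limma adjusted p of 0.813 and 0.327. Of 24 tested pluripotency genes 4 fell (Sox2, Tcl1, Dppa3 and Gbx2) and Fbxo15 rose, the same counts as adjusted over the list alone. Sox2 fell from 91.8 ± 5.31 to 70.1 ± 2.15 FPKM (SD, n = 4 each). Of 15 genes of primordial germ cell specification Sox2 and Dppa3 fell and 13 were not called, among them Tfap2c (43.2 and 49.1 FPKM) and Prdm14 (21.8 and 21.5 FPKM). Among 10 formative genes Otx2, a homeobox factor of the epiblast, rose from 2.47 ± 0.520 to 6.63 ± 0.385 FPKM (SD, n = 4 each), while Cdh2 and Zic2 fell. Adjusted over the list alone, the specification and formative lists had counts of 2 lower, and of 1 higher and 2 lower. None of these 3 lists was called (camera adjusted p of 0.14, 0.95 and 0.99), though the pluripotency list was with no filter on low values (0.028) and in the odd-numbered libraries alone (0.041). It had adjusted p = 0.5 with an estimated correlation. Single libraries ended the calls of Gbx2 (iPHet 1, 3 or 4, iPKO 1 or 3, limma adjusted p of 0.0517 to 0.0539), Cdh2 (iPHet 2 or 4, iPKO 1 or 3, 0.068 to 0.0781) and Zic2 (any except iPKO 2 or 4, 0.0552 to 0.0816).

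Markers of other lineages were mostly low and mostly not called. Of 7 neuroectoderm genes Olig2, Ncam1, Nes and Map2 fell and 0 rose, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.061, 0.024 with the replicate block and 0.03 with quantile normalization, but adjusted p = 0.5 with an estimated correlation). Map2 was not called with the block (limma adjusted p = 0.0516) or without iPHet 2, 3 or 4 or iPKO 2 or 4 (0.0511 to 0.0668). The call of Nes ended without iPHet 1, 2 or 3 or iPKO 2 or 4 (0.0514 to 0.0647), and that of Ncam1 without iPHet 2 or 4 or iPKO 1 or 3 (0.0569 to 0.0637). Of 10 trophoblast genes Ascl2 rose, or 2 genes adjusted over the list alone (camera adjusted p = 0.098, 0.039 with the block and 0.023 without iPKO 2, but adjusted p = 0.72 with an estimated correlation). Of 6 mesoderm genes Lefty2 fell, or 1 rose and 1 fell adjusted over the list alone (0.83). Lefty2 was not called without any single library except iPKO 4 (limma adjusted p of 0.0526 to 0.0955). Of 9 endoderm genes 0 were called, also adjusted over the list alone (0.79), including Apoe at 297 ± 98.8 and 181 ± 30.7 FPKM (SD, n = 4 each), which the block called with limma adjusted p = 0.0152 and the pair-averaged fit of protein-coding genes with an odd/even term did not (0.103). Of 7 markers of the embryonic fibroblasts used as feeders 0 were called, also adjusted over the list alone (0.99), with Fn1 at 232 ± 12 and 194 ± 51.1 FPKM (SD, n = 4 each). Of the two-cell-like genes 0 passed the filter. Xist was 0.0653 and 0.173 FPKM and was not tested.

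Of 14 FGF/ERK response genes Ier2, Myc, Spry2 and Etv5 fell and 0 rose (camera adjusted p = 0.22). Of 8 Wnt response genes Notum, a secreted Wnt inhibitor, fell from 33.3 ± 3.75 to 14.6 ± 1.62 FPKM (SD, n = 4 each) and Ccnd1 fell (0.20, and 0.043 with the block, but adjusted p = 0.68 with an estimated correlation). Gbx2 and Il6st fell among 11 LIF/STAT3 genes (0.34). Of 6 interferon genes Bst2 rose and Oas1a fell (0.95). Adjusted over the list alone, the counts were 4, 2, 3 and 1 lower, and 1 interferon gene was higher. Ccnd1, Spry2, Etv5, Gbx2, Il6st, Bst2 and Oas1a were not called without some single libraries, with the largest limma adjusted p at 0.0557 (iPHet 2), 0.0651 (iPHet 1), 0.107 (iPHet 4), 0.0539 (iPHet 1), 0.0697 (iPHet 2), 0.076 (iPKO 1) and 0.0837 (iPHet 4).

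Of 26 genes of Sm proteins and their assembly Snrnp200, a helicase of the U5 particle, rose from 75.8 ± 6.00 to 116 ± 13.1 FPKM (SD, n = 4 each). Strap, a component of the assembly complex, fell from 54.0 ± 2.60 to 42.5 ± 2.84 FPKM (SD, n = 4 each). Of 29 SR and hnRNP regulators 3 rose, Srsf11 and Srsf7 among them, and 3 fell, Srsf9 and Srsf6 among them, or 7 and 4 adjusted over the list alone. Of 12 other arginine methyltransferases and PRMT5 partners 0 were called, with Prmt6 at 11 ± 1.37 and 13.3 ± 0.689 FPKM (SD, n = 4 each). These lists were not called (camera adjusted p of 0.95, 0.70 and 0.99). Adjusted over the list alone, the methyltransferase count was 0, and the Sm counts were 1 and 1. Srsf6 was not called without iPHet 2 or 4 or iPKO 3 (limma adjusted p of 0.0505 to 0.0555), and Srsf7 without iPHet 4 (0.0548).

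Among cell cycle genes Mki67, Cdc20 and Ccnb2 fell, 3 of 21 in the G2/M list (4 adjusted over the list alone, camera adjusted p = 0.32). Without iPHet 4 the limma adjusted p of these genes were 0.0501, 0.0745 and 0.0827, and the calls of Cdc20 and Ccnb2 also ended without iPHet 1 or 2 or iPKO 1 or 3, and that of Ccnb2 without iPKO 4. Of 18 replication genes 0 were called, also adjusted over the list alone (0.50). With the replicate block Mcm7, Cdc6, Pcna and Ccne2 were lower (limma adjusted p of 0.0122, 0.00758, 0.0163 and 0.0359), but not in the pair-averaged fit of protein-coding genes with an odd/even term (0.248, 0.164, 0.399 and 0.286). Of 39 ribosomal protein genes 0 were called, also adjusted over the list alone (0.99). Their median log2 change was -0.42 in the odd-numbered libraries and 0.37 in the even-numbered ones.

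Of 22 tested imprinted genes, which are expressed from 1 parental copy, 5 rose and 1 fell, as also when adjusted over the list alone (camera adjusted p = 0.15). Grb10, an adaptor of insulin signalling, fell from 13.2 ± 0.384 to 6.06 ± 0.314 FPKM (SD, n = 4 each). Slc38a4 rose 2.08-fold and Nnat 2.43-fold, Impact rose from 48.7 ± 1.29 to 62.8 ± 0.173 FPKM (SD, n = 4 each), and Mirg and Zrsr1 rose as well. Nnat overlaps Blcap, and Slc38a4 was not called without iPHet 2 or 4 or iPKO 1 or 3 (limma adjusted p of 0.0544 to 0.0578). Zfp57, a zinc finger protein that protects imprints, rose from 451 ± 42.4 to 809 ± 130 FPKM (SD, n = 4 each). It was 1 of 2 genes of the DNA methylation machinery called among 17, also adjusted over the list alone (camera adjusted p = 0.20). The other was Tet2, whose call ended with the replicate block (limma adjusted p = 0.0585) or without iPHet 1, 2 or 3 or iPKO 1 or 3 (0.054 to 0.0768).

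Of 13 transcripts of the mitochondrial genome, mt-Nd2, mt-Nd1 and mt-Nd4l fell and 10 were not called, with the same counts adjusted over the list alone and a median log2 change of -0.31. The share of summed FPKM from this genome was 7.86% ± 0.99 in iPHet and 6.96% ± 1.4 in iPKO (SD, n = 4 each). The list had a camera adjusted p = 0.031, with adjusted p = 0.72 with an estimated correlation and 0.073 with quantile normalization. Leaving out iPHet 1 or 3 or iPKO 2 or 4 ended the call, with adjusted p of 0.11, 0.071, 0.084 and 0.074. The call of mt-Nd2 ended without iPHet 1 or 3 (limma adjusted p of 0.0519 and 0.0507) and that of mt-Nd1 without iPHet 1, 3 or 4 or iPKO 2 or 4 (0.064 to 0.0813). On the Y chromosome Ddx3y rose, Eif2s3y fell and Uty was not called, also adjusted over the list alone (camera adjusted p = 0.56). Eif2s3y was not called without any single library except iPKO 1 or 3 (limma adjusted p of 0.0728 to 0.0998). Of the 22 chromosomes 0 were called by camera, with 2 at an unadjusted p of 0.0061 (mitochondrial) and 0.0069 (Y). Without iPHet 2 or without iPHet 4 the count was 2, and without iPKO 1 it was 1.

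**Figure D4:**
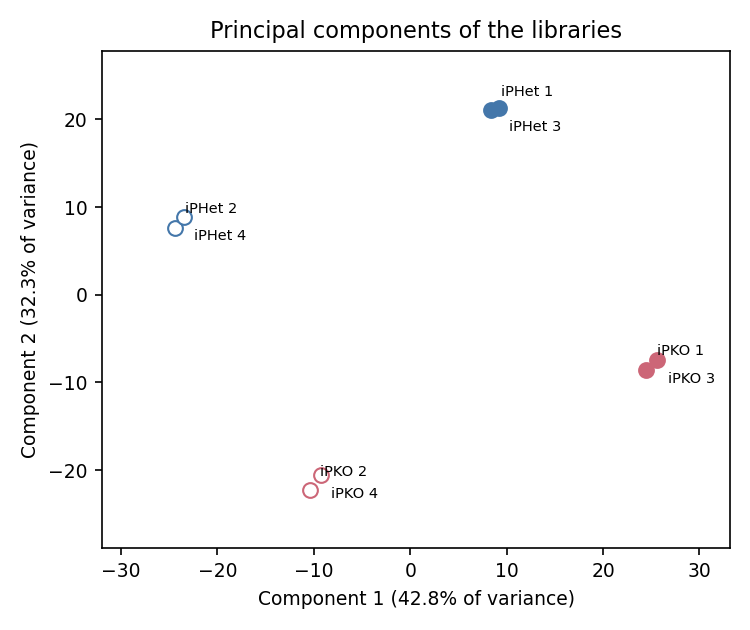
The 8 libraries on the first principal components of log2(FPKM + 1) over protein-coding genes, with filled points for odd and open points for even numbers. Component 1 holds 42.8% and component 2 holds 32.3% of the variance, and libraries 1 and 3, and 2 and 4, of each genotype lie close together.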

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

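The tests of the paired libraries, of odd or even libraries alone, of scaling and of single lists in other groupings were chosen only after the result was seen. Groups of 4 libraries were examined, 252 from 126 genes in each genotype and 14 more from 7 library measures. In 9 of them a library's gap to the nearest other exceeded 0.829 of the group's range. For 4 independent normal values chance gives about 1 in 20 such groups. That rate does not hold here, because libraries 1 and 3, and 2 and 4, of a genotype resemble each other. In iPHet 4, Dppa3 was 30.3 FPKM against 27.6 to 27.9 FPKM in the other iPHet libraries, Oas1a was 5.23 against 4.42 to 4.46 FPKM, Zbp1 was 1.77 against 2.33 to 2.43 FPKM and Xist was 0.054 against 0.0674 to 0.07 FPKM. Otx2 was 3.25 FPKM in iPHet 2 against 2.11 to 2.28 FPKM, and Lsm10 was 14.5 FPKM in iPHet 1 against 10.1 to 10.4 FPKM. Among iPKO libraries, Pycr1 was 3.41 FPKM in iPKO 4 against 2.16 to 2.23 FPKM, Nnat was 4.6 FPKM in iPKO 2 against 3.07 to 3.13 FPKM, and Prmt6 was 12.2 FPKM in iPKO 1 against 13.5 to 13.7 FPKM.

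Libraries 1 and 3, and 2 and 4, of each genotype resembled each other more than other libraries of that genotype did. Sequencing depth is argued against in iPHet, because iPHet 3 had a relative depth of 0.766 and iPHet 1 of 1, on either side of iPHet 2 and 4 at 0.881 and 0.816. It stays open in iPKO, where the odd libraries were deeper (1.24 and 1.11) than the even ones (1.08 and 0.87), by less than the libraries of a pair differed. The odd minus even differences of the genotypes correlated at 0.479 across 11171 protein-coding genes, which are not independent replicates, and at 0.17 across all 12462 tested genes, with a Spearman correlation of 0.396. The value over protein-coding genes is consistent with a harvest, library or run shared by both genotypes, while the Pearson value over all genes lies below the 0.2 set for protein-coding genes. Whether a pair is 1 culture sequenced again cannot be told apart from separate cultures. The lowest variance within a pair was 1.56 times that of the authors' bounds, whose calibration is unknown.

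The lower ATF4 list in iPKO was seen in both the odd- and the even-numbered libraries, with median log2 changes of -0.78 and -0.53. Of its 18 tested members, 14 had a negative genotype change in both sets and 0 a positive one in both. The larger of their camera p was 0.00024, but each of these tests sets 2 libraries that resemble each other against 2 others. The same tests called the ribosomal protein list in opposite directions, so such a p cannot show an effect of genotype. With quantile normalization the camera adjusted p of the ATF4 list was 0.00015, and in the main fit with an estimated correlation it was 0.5. Camera sets a list against all other genes and largely cancels a shift of all genes alike. The run with quantile normalization is therefore no test of such a scaling. The list also differed between odd and even libraries, lower in odd at an adjusted p of 0.0038 (0.38 with an estimated correlation), so a culture state that varies on its own may contribute. The labels name 1 line per genotype, so Prmt5 cannot be told apart from other differences between the lines.

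The higher later germ cell list had a median log2 change of 0.68 in the members with a mean of at least 5 FPKM, 4 in number, but these ran from -0.74 to 1.60 (SD 0.98), and only 2 of them reached that mean in iPHet. Their camera p was 0.048, so the bounds set beforehand, 0.05 for it and 0.2 for the median, were passed, but the p only narrowly. The median passed by less than that SD, which was not among those bounds and is a spread between genes, not a measure of noise. The 4 members thus met the prediction made for the absence of such noise. For the 12 members below 5 FPKM, noise of low genes stays open as a cause. Without paralogs of housekeeping genes the list's camera p was 1e-04 over 14 members. With quantile normalization its adjusted p was 0.006, and in the main fit with an estimated correlation it was 0.22. As for the ATF4 list, camera largely cancels a shift of all genes alike, so this is no test of such a scaling. A difference between the lines other than Prmt5, 1 line each, stays open here too.

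Of the 35 ways to part the 8 libraries into groups of 4, 2 gave at least the 1973 genes of the genotypes, so chance is not excluded. The other was odd against even numbers, with 2202 genes, which points to a structure of the samples. For genes changed at least 2-fold the number was also 2 of 35, with 116 genes for the genotypes and 203 for odd against even. For gene lists it was 20 of 35, with 4 lists for the genotypes and at most 9 elsewhere. Among the 8 ways that part all same-numbered libraries, the genotypes had the highest count, and the next, which crosses genotype with odd and even, gave 53 genes. The other 32 ways called 0 to 11 genes, but each parts libraries 1 and 3, or 2 and 4, of a genotype, which resemble each other. This raises the spread within groups, so their low counts were to be foreseen and lend the genotypes no weight. Only the genotypes, odd against even and the crossed way keep those pairs together. With the replicate number as a block the genotypes gave 3427 genes. By camera p, the ATF4 list was as low in 3 of the 35 ways, the later germ cell list in 1, the p53 list in 6 and the mitochondrial list in 11. Each count includes the genotypes, so the 1 of the later germ cell list is the genotypes themselves.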

How the results depend on the processing

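Pair averages, the odd/even term, correlated pairs, the restriction to protein-coding genes and the odd or even libraries alone were chosen only after the result was seen. Of 125 tested named genes 79 were called, 51 of them under every alternative chosen before the data were examined that was run on them (Dazl, Tex13, Nnat and Myc had no value with at least 5 FPKM), and 28 lost the call under at least 1, all of these also without at least 1 library. Counts of genes and of those changed at least 2-fold were 7 and 7 from pair averages (1126 at an unadjusted p under 0.05), 6 and 6 with an odd/even term as well, 52 and 21 with an estimated correlation of 0.84 within pairs, and 0 and 0 from pair averages of protein-coding genes (limma, 1041 unadjusted). They were 198 and 69 for those averages with an odd/even term, 5316 and 315 in odd and 4581 and 283 in even libraries alone. The replicate block gave 3427 genes and the odd/even term 4729. At least 2-fold were 278 genes with a pseudocount of 0.1 and 71 among protein-coding genes. Fewer samples or residual degrees of freedom enter the pair averages, and the cause of the other shifts was not tested. Prmt5, whose log2 change of -2.131 these balanced fits leave as it is by construction, had adjusted p of 0.191 from pair averages, 0.0809 with the odd/even term and 0.357 for protein-coding genes. It was called from protein-coding pair averages with the term (limma adjusted p = 0.00703) and in the fit with an estimated correlation within pairs.

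Called lists numbered 2 with at least 5 FPKM, where the later germ cell and mitochondrial lists each had 0.057. They numbered 7 with the replicate block, the odd/even term, and the pair averages with that term over all or protein-coding genes, and 8 in odd libraries. With an estimated correlation 0 were called, also from pair averages with the odd/even term. Those averages leave too few residual degrees of freedom for any list to be called so, and their 0 therefore decides nothing. In odd libraries 1 chromosome-wide shift was called, and the ribosomal protein list was lower (adjusted p = 4.3e-08), while in even libraries it was higher (5.9e-09). Rpl7 had a log2 change of 0.173 in even libraries, reversed from -0.23, and the cause was not tested. Quantile normalization ended the calls of 11 named genes and the mitochondrial list, and no filter on low values those of 11 named genes, Hpn (0.0642), Susd2 (0.0576) and Psat1 (0.0662) among them. Quantile normalization added the calls of 3 named genes and of the neuroectoderm list (0.03), and no filter that of the core pluripotency list (0.028). In odd libraries alone the core pluripotency (0.041), trophoblast (0.016), replication (0.016) and DNA methylation (0.041) lists were added, and in even ones the neuroectoderm list (0.036). A mean of at least 5 FPKM added 3 named genes, and limma without the trend added 2 and ended 2. Calls were gained by Pim3 without iPHet 2 (0.0258), Casp9 without iPKO 1 (0.0372), Ccnb1 without iPKO 2 (0.044), Lsm10 without iPKO 3 (0.029) and Snrpf without iPKO 4 (0.0391). The block ended the calls of Cycs, Map2 and Tet2 and of no other named gene, and it added 18 named genes, Eomes (0.00332), Sall4 (0.0185), mt-Cytb (0.0144) and Ccnb1 (0.0143) among them. In the pair averages of protein-coding genes with an odd/even term these 4 had 0.0702, 0.244, 0.344 and 0.296, and the 18 had 0.0702 to 0.477.

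Leaving out 1 library gave 1270 (without iPHet 4) to 1485 genes, 88 to 125 at least 2-fold, a Prmt5 log2 change of -2.207 to -2.058, 3 to 4 lists and 0 to 2 chromosome-wide shifts (2 without iPHet 2 or 4, 1 without iPKO 1). Isoform usage and a test across deposited units were not run, and the correlated-pair fit was not run for lists. The depth of the libraries is unknown, so low genes have an unknown counting error.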

Other observations

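The comparison of odd- with even-numbered libraries and its genes were chosen only after the result was seen, and the tests of neighbouring genes and of intron number were chosen before. Fitted here with a genotype term, the comparison called 4724 of 12462 genes, 2952 higher and 1772 lower in odd libraries. Member counts of lists are to be read against that share. The fit also takes libraries 1 and 3, and 2 and 4, of a genotype as separate although they resemble each other. Of 10 trophoblast genes 7 were higher and 0 lower in odd libraries, also adjusted over the list alone (camera adjusted p = 0.00071, and adjusted p = 0.08 with an estimated correlation). Of 22 imprinted genes 12 were higher and 4 lower, or 12 and 5 adjusted over the list alone, and the list was not called (adjusted p = 0.14). The means of libraries 1 and 3 against those of 2 and 4 were 76.5 and 17.5 FPKM in iPHet and 82.3 and 19.7 FPKM in iPKO for Krt8, a keratin of simple epithelia. H19, an imprinted noncoding RNA, had 28.5 and 5.86 FPKM in iPHet and 22.0 and 3.77 FPKM in iPKO, and its neighbour Igf2, a growth factor, had 33.3 and 5.27 FPKM and 26.1 and 6.31 FPKM. Cdx1, a Wnt-responsive homeobox gene, had 27.5 and 5.48 FPKM in iPHet and 18.3 and 4.21 FPKM in iPKO. Elf3, an epithelial transcription factor, had 105 and 36.7 FPKM in iPHet and 114 and 41.4 FPKM in iPKO. The cell cycle inhibitor Cdkn1a had 157 and 81.4 FPKM in iPHet and 161 and 90.6 FPKM in iPKO.

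Of 14 FGF/ERK response genes 4 were higher and 7 lower in odd libraries, or 5 and 7 adjusted over the list alone, and the list was not called (camera adjusted p = 0.16). Phlda1 had 5.62 FPKM in odd and 2.84 FPKM in even iPHet libraries, and 6.02 and 3.96 FPKM in iPKO, and Spry1, Spry2 and Dusp5 were also higher in odd. Etv4 had 8.26 FPKM in odd and 18.4 FPKM in even iPHet libraries, and 5.63 and 22.5 FPKM in iPKO. Dusp6, a phosphatase of ERK, had 3.67 and 7.23 FPKM in iPHet and 1.99 and 5 FPKM in iPKO. Vim, an intermediate filament gene, had 30.9 and 54.2 FPKM in iPHet and 10.2 and 46.2 FPKM in iPKO. Of 18 replication genes 0 were higher and 13 lower in odd libraries, or 0 and 14 adjusted over the list alone, with a median log2 difference of -0.25 (camera adjusted p = 4.2e-07, and adjusted p = 0.049 with an estimated correlation, the only list called so). Of 21 mitotic genes 0 were higher and 14 lower, or 0 and 15 adjusted over the list alone, with a median of -0.27 (camera adjusted p = 4.2e-07, and adjusted p = 0.069 with an estimated correlation). Of 13 mitochondrial transcripts 11 were higher and 0 lower, or 12 and 0 adjusted over the list alone, with a median of 0.4 (camera adjusted p = 0.0016, and adjusted p = 0.12 with an estimated correlation). The trophoblast median was 0.99. The SR and hnRNP (0.00072), formative (0.008), Sm protein (0.01) and ATF4 (0.0038) lists were also lower and the endoderm list (0.04) higher in odd libraries, with adjusted p = 0.14, 0.12, 0.38, 0.38 and 0.26 with an estimated correlation.

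Peg10, an imprinted gene of the placenta, was listed at 0 FPKM in iPHet 1, iPHet 3 and iPKO 2, at 22.3 and 21.4 FPKM in iPHet 2 and 4, at 129 and 116 FPKM in iPKO 1 and 3, and at 19.9 FPKM in iPKO 4. Of 39 ribosomal protein genes 2 had a positive and 2 a negative genotype change in both sample sets, with medians of -0.42 in odd and 0.37 in even libraries, and the difference was not tested. Rps28 had a log2 change of -1.26 in odd and 0.74 in even libraries, and Rps29 of -1.21 and 0.65.

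A hypothesis that transcripts with many introns were lower in iPKO, since PRMT5 modifies splicing proteins, was tested across 11171 protein-coding genes, which are not independent replicates. The Spearman correlation of the log2 change with intron number was 0.242 in odd and -0.0579 in even libraries. The negative correlation predicted for both sets was therefore not seen. For the length of the longest transcript it was 0.259 and -0.0929, so an effect of introns was not separated from one of length. Because of this the values cannot decide the hypothesis. Another hypothesis was that copy number differences between the lines set the changes of neighbouring genes. Across 10145 adjacent pairs the Spearman correlation was 0.0754, above the -0.029 to 0.034 of 1000 shuffled orders and below the 0.1 set beforehand, so it stays open.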
